A study of Rattus norvegicus with 12 samples.

How the data were processed

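Messenger RNA was measured by strand-specific RNA sequencing in 12 libraries of OC1 cells, which the labels describe as a sensory epithelial line of the cochlea. The cells had been transfected with a negative control siRNA or with one of 2 siRNAs against Bcl-2, coded 1423 and 1928 in the labels. The labels conflict on the reagent: their treatment tag names a plasmid, while their protocol and descriptions name siRNA, which is followed here. The siRNA code in each title set the group, which gave 3 groups of 4 libraries, and the letters A to D in the titles named the replicates. One control library, replicate B, carries the extra letters NC in its description and was kept in the control group on its title. Nothing in the labels says that the replicates were separate cultures, so every p-value measures only the spread between these samples, which may be technical. Organism and genome build are rat and mRatBN7.2 in the submitters' notes. A line with a similar name, HEI-OC1, is of mouse origin, and the sources used here do not settle whether OC1 is that line.

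The deposited values are expected counts (estimated read counts) per Ensembl gene ID for 23978 rat genes, with 1 column per library and 0 columns from other samples. Their unit was read from the values: 71.3% were whole to within 1e-06, the others had up to 3 decimals, and the library totals differed. The submitters' processing notes list bcl2fastq 2.20, fastp 0.21.0 and DESeq2 1.24.0. The aligner, the program that estimated the counts and the annotation release are not given in the sources used here. How reads shared by near-identical genes were divided is likewise not given, so members of multigene families carry an uncertainty that was not measured. The library protocol in the labels marks strand, but whether the counting used it is not given.

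The files do not pair the gene IDs with symbols. A reference table of rat genes from assembly GRCr8 was searched for a match, and 0 of the IDs were found in it. Bcl2 itself, the target of both siRNAs, was therefore not analysed here, and its level was not used to check the sample labels. Gene lists fixed before the data were examined, 36 in number, could not be assigned either and were not used here. The planned rule for naming genes asked for a symbol, an adjusted p under 0.05, a mean of 5 counts per 1000000 (CPM) or more, and all 4 libraries of a group on one side of all 4 control libraries. Without symbols, the rule was applied to the genes changed in the same direction by both siRNAs, and only the 2 IDs with the highest and the 2 with the lowest mean log2 fold change over both contrasts are printed. Other genes are described as groups set by direction, size and abundance.

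Expected counts were rounded to whole numbers. Genes were kept by the filterByExpr function of edgeR with its default minimum count of 10 and minimum total of 15, which left 12731 genes holding 99.95% of all counts. Of the 11247 genes left out, 5685 were at 0 in every library. Counts were scaled with trimmed means of M values (TMM) and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3). A single model with 1 mean per group was fitted to all 12 libraries, so that the 3 contrasts shared 1 estimate of the spread. P-values were adjusted by Benjamini and Hochberg over all tested genes in each contrast, and a gene is called changed at an adjusted p under 0.05. CPM are scaled by TMM, and principal components were taken from log2 CPM with a prior count of 2. Standard errors of log2 fold changes were derived from the F statistic. Values per library, such as totals, were compared by exact two-sided permutation tests of 4 against 4 libraries, which cannot give a p under 0.0286 and were adjusted over 9 tests of library measures and 6 tests of the share of counts in scarce genes. Figures were drawn with matplotlib 3.10.9.

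Library totals ran from 15671546 to 23247593 expected counts. The biological coefficient of variation over all tested genes was 3.95%, and the median standard error of a log2 fold change was 0.186 in the lowest of 4 equal bins of genes by abundance and 0.035 in the highest, for siRNA 1423 against control. Before any averaging, pairs of libraries were compared by a chi-square test of their counts over genes. All 18 pairs within a group differed by 1.94 to 5.90 times the sampling noise, so no library was a copy of another. Each was counted as its own sample, although this does not show that they came from separate cultures. The closest pairs were A with B and C with D for siRNA 1423 (1.94 and 2.27) and for siRNA 1928 (2.42 and 1.99). In the control group C with D was closest (2.31), but A with B (3.20) was further apart than B with D (2.71).

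The fits were tested on simulated counts of 12635 genes, drawn from the means and totals of these libraries. Known changes of each size were placed in 98 to 100 of these genes per contrast. At a log2 size of 1, edgeR recovered 95 of 100 changed genes for siRNA 1423 against control and 91 of 100 for siRNA 1928 against control. At a log2 size of 0.25 it recovered 55.6% and 58.2%. False calls numbered 11 among 161 and 6 among 154. Far fewer genes changed there than in the real contrasts, which makes the adjusted threshold stricter, so these rates do not measure the sensitivity of the real fits.

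The alternatives set before the data were examined were the DESeq2 Wald test (DESeq2 1.42.0), limma voom, size factors by relative log expression, library size alone, no filter on low counts, a filter of 1 CPM in 4 libraries, the replicate letter as a block, a fit to only the 8 libraries compared, each library left out in turn, a 2-fold limit and, for results over both siRNAs, controls split between the contrasts. Fits to only replicates A and B, to only C and D, and with that division of the letters as a covariate were added after the data had been seen. Both contrasts against control use the same 4 control libraries, so the overlap of their calls was also computed for 50 simulated sets of unchanged groups and for lists taken as independent.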

Results

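The transcriptome of OC1 cells, a cultured line labelled as sensory epithelium of the cochlea, was measured after transfection with siRNA against Bcl-2, an inhibitor of apoptosis at the mitochondrial membrane. An siRNA is a short double-stranded RNA that directs the degradation of mRNAs with a matching sequence. Cells received a negative control siRNA, siRNA 1423 or siRNA 1928, with 4 libraries in each group. Library totals were 20105438 ± 3097776 expected counts in the control group (SD, n = 4), 18803766 ± 2422996 with siRNA 1423 (n = 4) and 19603345 ± 3242752 with siRNA 1928 (n = 4). The totals of the 3 pairs of groups did not differ detectably by an exact permutation test (p = 0.514, 0.8 and 0.743, with adjusted values of 0.771, 0.9 and 0.9). Genes with at least 10 expected counts numbered 12582 ± 166 per control library, 12468 ± 98.8 per library of siRNA 1423 and 12720 ± 164 per library of siRNA 1928 (SD, n = 4 each). Because the gene IDs come without symbols, the level of Bcl2 is not among the values analysed here, and genes are described by group and, for 4 of them, by ID.

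The libraries separated by the siRNA the cells had received. On the first principal component, which held 34.9% of the variance, the 4 libraries of siRNA 1928 lay between 19.9 and 22.1 and the 8 others between -11.9 and -9.51. The second component, with 14.5%, separated the control libraries at 9.68 to 15.5 from those of siRNA 1423 at -12.6 to -9.0, with siRNA 1928 between them at -2.07 to 1.43. Correlations of log2 CPM ran from 0.996 to 0.998 within groups (18 pairs) and from 0.991 to 0.996 between groups (48 pairs). The third component, with 9.48%, set replicates A and B apart from C and D in every group. With this division of the letters as a term beside the group, edgeR called 1115 genes, with a median absolute log2 difference of 0.13. The other 2 ways of dividing the letters into pairs each gave 0 genes by edgeR and by limma voom, with 277 and 278 at an unadjusted p under 0.05. Counts of changed genes are therefore also given for replicates A and B alone and for C and D alone.

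**Figure D1:**
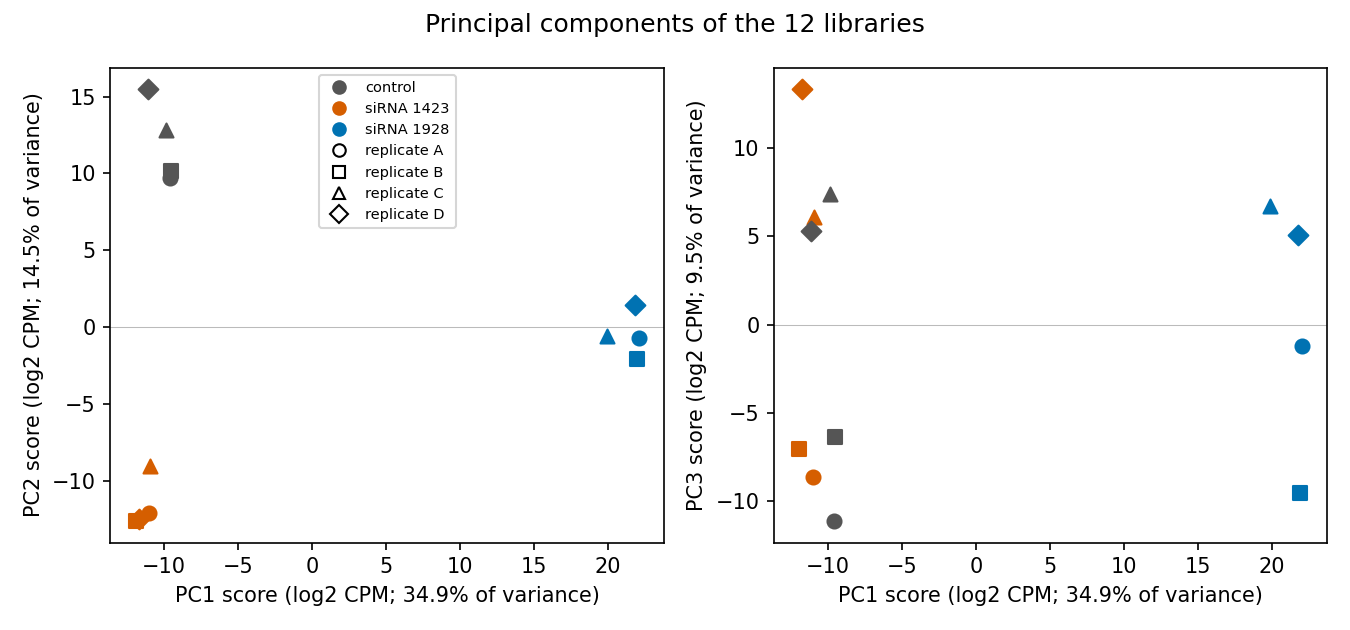
Principal component scores of the 12 libraries from log2 CPM, with color for the siRNA and marker shape for the replicate letter; the left panel plots component 2 against component 1 and the right panel component 3 against component 1. The libraries of siRNA 1928 lie between 19.9 and 22.1 on component 1, and replicates A and B lie below 0 and C and D above 0 on component 3.

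The comparison of siRNA 1423 with control addressed which transcripts changed in cells given this siRNA. Of 12731 genes tested, 2903 changed (22.8%), of which 1436 were higher and 1467 lower. The changes were small, with a median absolute log2 fold change of 0.20 with 10th and 90th percentiles of 0.12 and 0.45. Only 11 of the increases and 31 of the decreases reached 2-fold, and 58 increases and 109 decreases reached 1.5-fold. Scarce transcripts made up most of these, since all 11 of the 2-fold increases and 29 of the 2-fold decreases came from genes with a mean under 10 CPM. The share of changed genes grew with abundance, from 7.48% in the lowest of 4 equal abundance bins (under 10.1 CPM) to 36.5% in the highest (78.5 CPM or more), while the median standard error of all genes fell from 0.186 to 0.035. In 2419 of the changed genes every library of siRNA 1423 lay on the same side of every control library. Such separation was seen in 23.7% of all tested genes, against 2.86% by chance. The 10 most abundant genes of each library took 7.10 ± 0.0368% of the counts with siRNA 1423 and 6.69 ± 0.0873% in the control group (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0643). Replicates A and B alone gave 1535 changed genes, fewer by more than 1.5 times, and replicates C and D alone gave 2361. Of these, 1427 and 2002 were among the 2903.

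The same question was asked of siRNA 1928, which changed more genes. Against control, 5752 genes changed (45.2%), with 2780 higher and 2972 lower. Their median absolute log2 fold change was 0.25, with 10th and 90th percentiles of 0.12 and 0.64. A 2-fold change was reached by 73 increases and 75 decreases, and a 1.5-fold change by 335 and 380. Among genes with a mean of 10 CPM or more, 40 fell at least 2-fold, which was 93.0% of the 2-fold changes in that range, and at 1.5-fold or more 281 fell and 64 rose (81.4% decreases); with library size alone 209 fell and 93 rose (69.2%). Among genes under 10 CPM, 70 rose and 35 fell at least 2-fold, and 271 rose and 99 fell at least 1.5-fold. The 40 abundant genes that fell had a median log2 fold change of -1.22 with siRNA 1928, and all 40 were lower in each of its 4 libraries than in every control library. Their median with siRNA 1423 was -0.12. All 40 differed between the siRNAs, 19 of them also fell with siRNA 1423, with not one of those falls reaching 2-fold, and 1 rose with it. Separation of all 4 libraries from all 4 controls was seen in 39.4% of the tested genes, against 2.86% by chance, and in 4705 of the changed genes. The balance of higher and lower calls depended on the scaling. TMM factors averaged 1.03 with siRNA 1928 and 0.988 in the control group (exact permutation p = 0.0286, adjusted p = 0.0643, n = 4 each), and 48.3% of the changed genes were higher with TMM, against 64.4% of 6005 genes with library size alone. Replicates A and B alone gave 4446 changed genes and C and D alone gave 4776. Decreases made up 93.2% and 95.6% of the 2-fold changes at 10 CPM or more in these 2 parts, and increases 66.4% and 71.3% of those under 10 CPM.

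**Figure D2:**
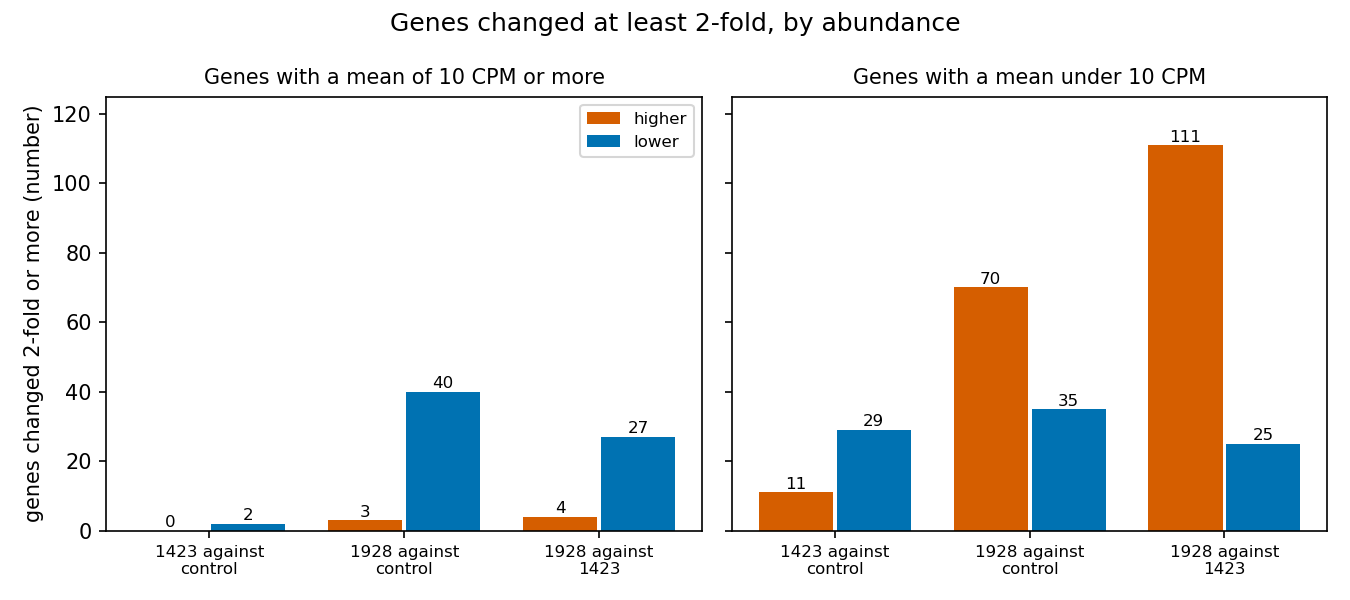
Number of genes changed at least 2-fold in each contrast (adjusted p under 0.05), drawn as bars for higher and lower genes, with genes of a mean of 10 CPM or more on the left and under 10 CPM on the right. Against control, 40 genes fell with siRNA 1928 in the left panel, and 70 rose and 35 fell in the right panel.

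The direct comparison of siRNA 1928 with siRNA 1423 asked where the responses to siRNAs against the same target differed. Between them, 5645 genes differed (44.3%), with 2714 higher and 2931 lower with siRNA 1928. The median absolute log2 difference was 0.26. Differences of at least 2-fold numbered 115 higher and 52 lower. Under 10 CPM, 111 genes were at least 2-fold higher and 25 lower with siRNA 1928, and at 10 CPM or more 27 genes were lower and 4 higher. With library size alone the latter numbers were 20 and 7, and at 1.5-fold or more the balance at 10 CPM or more went from 225 lower and 96 higher to 156 and 156. All libraries of one siRNA lay on one side of all libraries of the other in 39.9% of the tested genes, against 2.86% by chance. With library size alone, 66.4% of 6062 genes were higher with siRNA 1928, against 48.1% with TMM. Replicates A and B alone gave 4150 genes and C and D alone gave 4743.

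Changes shared by both siRNAs were compared with those particular to one. Both siRNAs changed 1834 genes, and 1437 of these (78.4%) moved in the same direction, 672 higher and 765 lower. Independent lists of the same lengths would share 314 higher and 342 lower genes if all genes were equally likely to be called. The share called rose from the lowest to the highest abundance bin in both contrasts, from 7.48% to 36.5% with siRNA 1423 and from 23.5% to 60.7% with siRNA 1928. This raises the overlap that independent lists would have, by an amount not computed here. Simulated unchanged groups measured against the same controls shared 0.06 genes on average over 50 simulations, but edgeR called only 0.68 and 0.4 genes per contrast there, so this value sets no level for contrasts with real changes. In the 672 genes that rose with both, the median log2 fold change was 0.20 with siRNA 1423 and 0.25 with siRNA 1928. In the 765 that fell with both, the medians were -0.21 and -0.28. The siRNAs differed in the size of the change in 243 of the former, 188 of them changed more by siRNA 1928, and in 348 of the latter, 286 of them changed more by siRNA 1928. When the controls were split, with 2 libraries for each contrast, 776 to 990 genes moved in the same direction over the 6 ways of splitting. Replicates A and B alone gave 766 such genes and C and D alone gave 1123.

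Another 397 genes moved in opposite directions. The difference between the siRNAs passed the test for all 397, which follows almost by construction from opposite calls in one fit and is no further evidence. Of these, 238 were higher with siRNA 1423 and lower with siRNA 1928, with medians of 0.16 and -0.18 on the log2 scale, and 159 were lower with siRNA 1423 and higher with siRNA 1928, with medians of -0.24 and 0.23. Independent lists, with all genes equally likely to be called, would give 656 genes in opposite directions. The simulated unchanged groups gave 0 by edgeR (0.5 on average at an unadjusted p under 0.05 in both contrasts, against 658 observed). Hardly any gene was called there, so these values likewise set no level for contrasts with real changes. With split controls 210 to 392 genes moved in opposite directions, and replicates A and B alone gave 149 and C and D alone 259. Genes that changed with siRNA 1423, did not pass the test with siRNA 1928 and differed between the siRNAs numbered 385 higher and 397 lower. The corresponding genes of siRNA 1928 were 1444 higher and 1572 lower. In 287 and 902 more genes, changed with siRNA 1423 alone and with siRNA 1928 alone, the difference between the siRNAs did not pass the test.

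Across all tested genes, which are not independent replicates, the log2 fold changes of the 2 siRNAs had a Pearson r of 0.339 and a Spearman rho of 0.315. A single scarce gene, with log2 fold changes of 6.32 with siRNA 1423 and 6.19 with siRNA 1928, adds to r and to the covariance. Its part in them was not computed. Shared controls alone gave a mean r of 0.497 in the simulated unchanged groups, where all variation is noise by construction. The covariance was 0.0239, against 0.00824 in the simulation, a difference of 0.0157. With split controls, r was 0.150 to 0.198 and the covariance 0.0127 to 0.0159. Within replicates A and B r was 0.307, and within C and D it was 0.372.

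**Figure D3:**
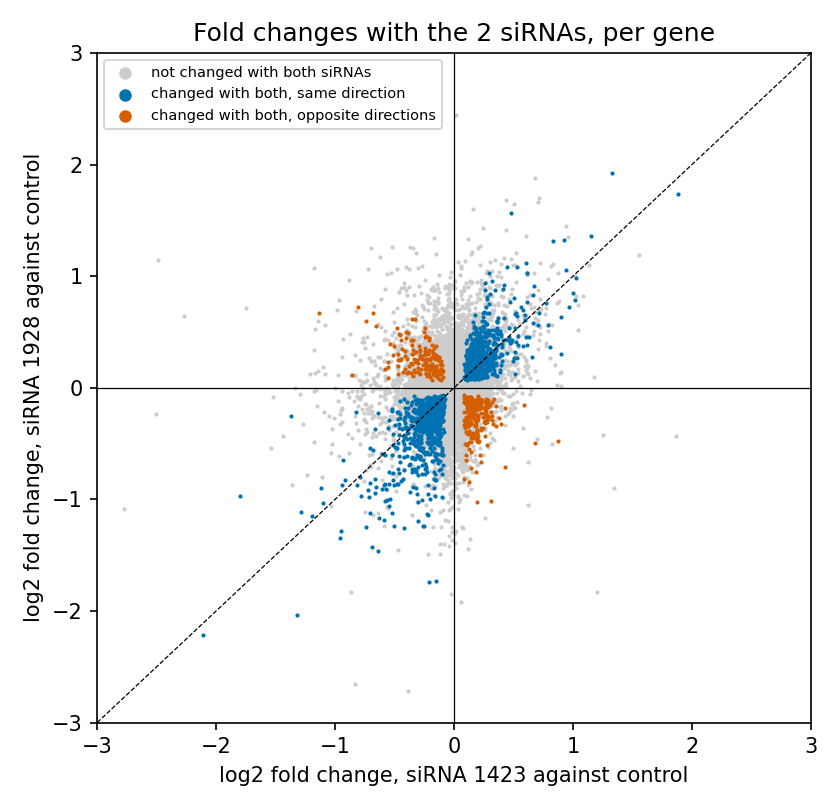
Log2 fold change against control with siRNA 1928 (vertical axis) and with siRNA 1423 (horizontal axis), 1 point per tested gene, with genes changed by both siRNAs in blue where the direction was shared and in orange where it was opposite; the dashed line marks equal changes and 1 gene lies outside the axes. The 1437 blue points fill the lower left and upper right quadrants, and the 397 orange points the others.

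Among the genes changed in the same direction by both siRNAs, 1068 averaged 5 CPM or more and had no overlap with the control libraries in either contrast. The largest called log2 fold changes, 6.32 with siRNA 1423 and 6.19 with siRNA 1928, belonged to the same gene, which lay under this floor. It was the only 1 beyond 3 on the log2 scale with either siRNA. Both siRNAs reached 2-fold in 4 of the genes that rose with both and in 5 of those that fell with both, none of them among the IDs given here. Within the 1068, the largest mean increase was that of ENSRNOG00000053406, at 11.2 ± 0.430 CPM in the control group, 16.2 ± 0.489 with siRNA 1423 and 23.8 ± 0.667 with siRNA 1928 (SD, n = 4 each). Its log2 fold changes were 0.53 (SE 0.0641, adjusted p = 2.8e-06) and 1.08 (SE 0.0607, adjusted p = 2.37e-12). ENSRNOG00000017307 rose from 53.2 ± 2.61 CPM to 72.5 ± 3.82 with siRNA 1423 and 113 ± 3.39 with siRNA 1928, or by 0.45 (SE 0.0438, adjusted p = 1.56e-07) and 1.08 (SE 0.0421, adjusted p = 3.55e-15) on the log2 scale. The deepest mean decrease within the 1068 was in ENSRNOG00000000704, from 12.1 ± 1.27 CPM to 6.24 ± 0.572 with siRNA 1423 and 4.94 ± 0.795 with siRNA 1928, with log2 fold changes of -0.95 (SE 0.110, adjusted p = 1.46e-06) and -1.28 (SE 0.113, adjusted p = 4.28e-09). ENSRNOG00000043377 fell from 552 ± 19.6 CPM to 342 ± 4.32 and 205 ± 1.78, with log2 fold changes of -0.69 (SE 0.0283, adjusted p = 1.15e-13) and -1.43 (SE 0.0291, adjusted p = 1.08e-19). The 4 were picked by their mean change, and log2 fold changes over all tested genes varied more with siRNA 1928 (variance 0.0969) than with siRNA 1423 (0.0513). The choice therefore favored genes that changed far with siRNA 1928. All 4 changed further with siRNA 1928 than with siRNA 1423, by log2 differences of 0.55, 0.64, -0.33 and -0.74 in the order given. The third of these differences, that of ENSRNOG00000000704 (SE 0.125, adjusted p = 0.0337), no longer passed the test with library size alone, with replicates A and B alone, without replicate A, C or D of siRNA 1423, or without replicate B or D of siRNA 1928, where it lay between -0.34 and -0.17 with adjusted p-values of 0.051 to 0.451.

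**Figure D4:**
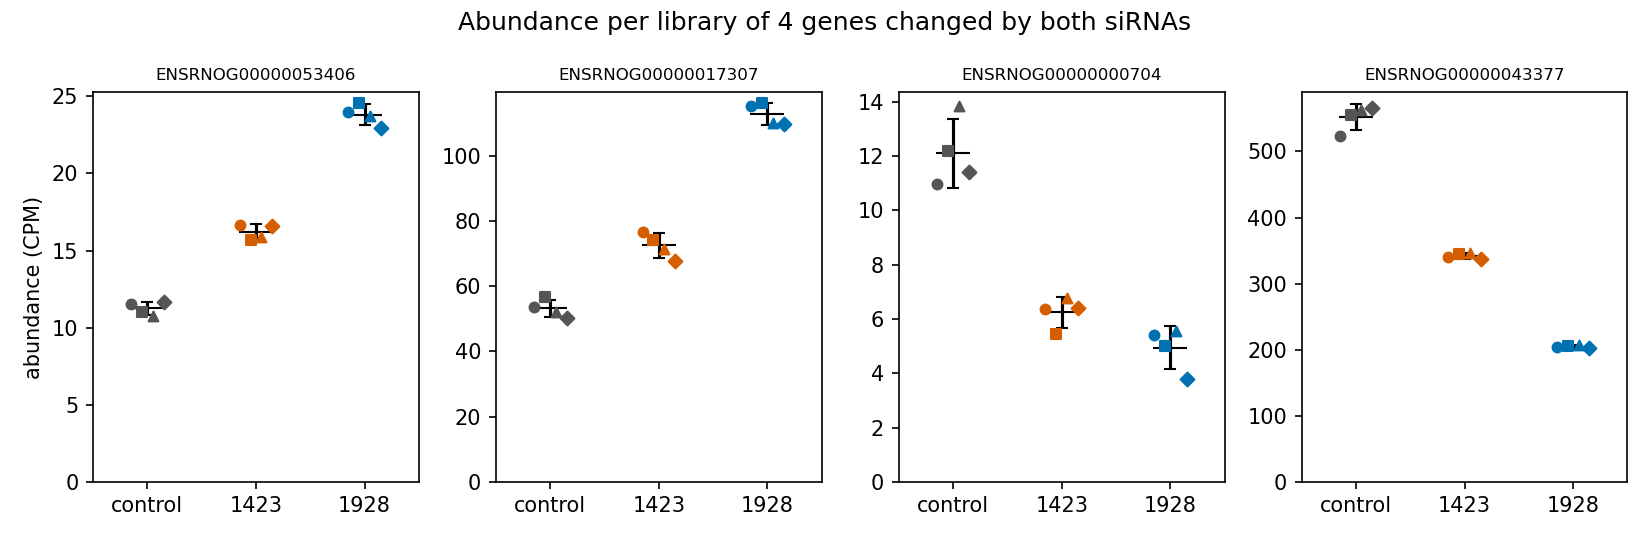
Abundance in CPM of 4 genes changed by both siRNAs, with 1 point per library shaped by replicate letter and the mean and SD of each group (n = 4) as a black bar. The first 2 genes rise from control to siRNA 1423 to siRNA 1928, reaching 23.8 and 113 CPM, and the last 2 fall, to 4.94 and 205 CPM.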

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

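The tests of a larger shared response, of calls kept without each library of siRNA 1928 and of reads spread evenly over genes, and the permutation test of the share of counts in genes left out, were chosen only after the results were seen, and the count of genes moving in opposite directions was not among the results set beforehand. Also not set beforehand were the 1.5-fold shares with library size alone, the measure of differing genes for siRNA 1928, and the separation of the decreases from the control libraries. The other tests in this part, with their bounds, were set before they were run. The patterns of 2-fold changes with siRNA 1928 above and below 10 CPM, and that limit itself, were not among the results set beforehand. They were taken from the results.

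Several results stood out because the 2 siRNAs differed. Genes moving in opposite directions numbered 397, and the difference passing the test for each follows almost by construction from the opposite calls. The 4 genes given by ID differed in the size of their change, by 0.55 for ENSRNOG00000053406, 0.64 for ENSRNOG00000017307, -0.33 for ENSRNOG00000000704 and -0.74 for ENSRNOG00000043377 on the log2 scale (siRNA 1928 minus siRNA 1423). Their choice by mean change over both siRNAs favored genes that changed far with siRNA 1928. The difference for ENSRNOG00000000704 lost its call without replicate A (-0.33), C (-0.29) or D (-0.32) of siRNA 1423 and without replicate B (-0.34) or D (-0.23) of siRNA 1928. Replicate C of siRNA 1423 lay far from the other libraries of its group in the number of genes with 10 or more expected counts (12615) and with any count (15374). It was also the deepest library of its group, at 22017957 expected counts. Chance picks out about 1 in 20 of the 33 groups of values searched this way. Genes left out by the low-count filter, and so outside the contrasts of the report, held a mean of 0.0521% of the counts with siRNA 1928, and each of its 4 libraries lay above every control library.

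The first pattern weighed is that siRNA 1928 changed more genes than siRNA 1423. Library depth is opposed by thinning every library to the smallest total, 15671546 expected counts, which left a ratio of 2.03 between the counts of changed genes (5466 and 2695). With library size alone the ratio was 2.07, so TMM did not create the excess. TMM had brought the median log2 fold change with siRNA 1928 to 0.0034, from 0.0599 with library size alone. Leaving TMM out was therefore unlikely to lower the count of siRNA 1928, and this ratio does not decide on composition scaling. A single response that siRNA 1928 drives further is opposed as the whole account by the 21.6% of genes changed by both that moved in opposite directions. What stays open is a difference in the depth of the Bcl-2 knockdown, which was not analysed here. Effects of each siRNA apart from its target also stay open and may add to either count. So do another offset of the scaling and differences between cultures or transfections that coincide with the groups. The labels do not say that the replicates were separate cultures.

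The second pattern is that 2-fold changes of genes at 10 CPM or more with siRNA 1928 were mostly decreases. Their share was 91.7% with library size alone and 92.9% after thinning, against what scaling or depth would need, although at 1.5-fold or more the share fell from 81.4% to 69.2% with library size alone. Leaving out each library of siRNA 1928 in turn kept both the call and the 2-fold size for 87.5% of the decreases (35 of 40), just under the 90% set beforehand as the bound. By that bound the test left a single library undecided. Values examined afterwards oppose it: the call held in all 4 fits for 100% of the decreases, and the smallest fall in any fit was -0.96 on the log2 scale. All 40 were also lower in each library of siRNA 1928 than in every control library, although these genes had been picked by call and size. As a hypothesis, siRNA 1928 may silence other mRNAs that match part of its sequence. This stays open because no siRNA sequence or 3' UTR was used here. With siRNA 1423, decreases were 70.7% (29 of 41) of the 1.5-fold changes at 10 CPM or more that differed between the siRNAs. With library size alone they were 76.2% (32 of 42). Both shares lay under the 80% set beforehand as what such silencing would give. The same measure for siRNA 1928 was 81.8% of 330 with TMM but 69.3% of 290 with library size alone. Which siRNA had the larger share thus depended on the scaling.

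The third pattern is that 2-fold increases outnumbered decreases among genes under 10 CPM with siRNA 1928. Increases stayed at 64.3% of these changes after thinning, which opposes depth, and were 74.8% with library size alone. TMM lowered the fold changes of siRNA 1928, with a median log2 value over all tested genes of 0.0034 against 0.0599 with library size alone. TMM therefore did not create the excess of increases. That outcome was fixed by the direction of the factors, and another offset of the scaling was not tested. Reads from outside the tested genes may contribute, since the share of counts in genes left out of the test was 1.2 times that of the control group and higher in all 4 libraries of siRNA 1928 than in the 8 others (exact permutation p = 0.0286, adjusted p = 0.0429, against control). Reads spread evenly over all genes were examined over all detected genes with no filter, after other forms of the test had been dropped. Genes of 1 to 10 CPM gained a mean of 0.363 CPM and those under 1 CPM 0.0265 CPM, a ratio of 13.7 (at least 3.87 between single libraries). These CPM were scaled by library size alone, where the median log2 fold change with siRNA 1928 over all tested genes was 0.06. Such a rise in proportion gives more CPM to more abundant genes, so the ratio does not decide. Reads spread evenly or unevenly stay open, as does whether the rise belongs to transcription or to the make-up of the RNA. No biological explanation was tested beyond the siRNA itself.

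Other divisions of the same libraries were tried for each count. Of the 35 ways to divide the 8 libraries of a contrast, 1, the real one, gave as many genes in each contrast: 2903 for siRNA 1423 against control with at most 2 in any other, 5752 for siRNA 1928 against control and 5645 between the siRNAs with 0 in every other by edgeR. At an unadjusted p under 0.05 the real counts were 4335, 6588 and 6461, and the highest of the others were 2023, 1819 and 1855. Of 100 assignments of the 12 libraries to 3 groups, the real one included, 1 gave as many as 1437 genes in the same direction and 1 as many as 397 in opposite directions, with 0 in every other by edgeR (at most 1141 and 183 at an unadjusted p under 0.05, against 2124 and 658). No second tool was run on these divisions. The real assignment thus ranked first for each count, and for a contrast 1 of 35 is the smallest share such divisions allow. Mixed divisions join libraries of groups that differ, which widens the spread, so the near absence of calls in them is no further evidence. Chance assignment of libraries is therefore not excluded.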

How the results depend on the processing

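The fits within replicates A and B, within C and D and with that division as a covariate, and all alternatives for the genes in opposite directions, were chosen after the data had been seen. Over the choices of tool, scaling, filter and block and, for the contrasts alone, of only the 8 libraries compared, changed genes numbered 2691 to 3365 (siRNA 1423 against control), 5385 to 6174 (siRNA 1928 against control), 5293 to 6062 (between the siRNAs) and 1318 to 1688 (same direction). Leaving out 1 library at a time gave 2350 to 2862, 5210 to 5498, 5068 to 5329 and 1126 to 1413, with 292 to 372 genes in opposite directions and r from 0.285 to 0.361. A 2-fold limit cut the counts by construction to 42, 148, 167, 9 in the same direction and 0 in opposite directions by edgeR (1 at an unadjusted p under 0.05, 1 by limma voom, 0 by DESeq2). Replicates A and B alone, with fewer samples, gave 1535 genes for siRNA 1423, 766 in the same direction and 149 in opposite directions, and C and D alone gave 259 in opposite directions. Controls split 2 and 2 gave medians of 834.5, 230 and an r of 0.179, with fewer control libraries behind each contrast. Without a low-count filter r was 0.447; the cause was not tested.

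The letters were not taken to pair the samples: 5 of 12 same-letter pairs had a correlation of deviations above 0.1 (range 0.0296 to 0.134), and 2 libraries correlated best with their own letter in both other groups. The replicate block gave 3365, 6174, 6017, 1688 and 486 genes, and r of 0.341, all within 1.5 times the unblocked values. The covariate for A and B against C and D gave 3549, 6328, 6164, 1791 and 522. Of the 4 genes given by ID, 3 kept direction and call in all 19 settings of each of the 3 contrasts; ENSRNOG00000000704 lost the call in 7, all between the siRNAs, and none changed direction. Other settings listed beforehand for Bcl2 and for the gene lists were not run, because the IDs are not paired with symbols. Depth limits the scarcest genes most: the median standard error for siRNA 1928 against control was 0.181 in the lowest of 4 abundance bins and 0.0348 in the highest.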

Other observations

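The tests in this part were chosen after the results were seen.

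Genes that switched between 0 and detection were few. With siRNA 1928, 7 genes had counts in all 4 libraries and 0 in all 4 control libraries, and 8 showed the opposite. With siRNA 1423, 13 genes detected in all 4 control libraries were at 0 in all 4 libraries, and 4 showed the opposite. Between the siRNAs, 20 genes were at 0 in all libraries of siRNA 1423 and detected in all of siRNA 1928, and 5 showed the opposite.

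Scarce transcripts as a class lay slightly higher with siRNA 1928. Tested genes under 10 CPM, 3164 in number, together held 1.19 ± 0.0233% of the counts with siRNA 1928, 1.09 ± 0.0209% in the control group and 1.08 ± 0.0192% with siRNA 1423 (SD, n = 4 each). The exact permutation p was 0.0286 for siRNA 1928 against each of the others (adjusted p = 0.0429), the smallest that 4 against 4 libraries allow. Their median log2 fold change against control was 0.08 with siRNA 1928 and -0.03 with siRNA 1423. Of the 70 that rose at least 2-fold with siRNA 1928, 47 differed between the siRNAs, 11 also rose with siRNA 1423, and 46 had fewer than 20 expected counts in every control library.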
